A study of Mus musculus with 16 samples.

How the data were processed

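RNA was measured in 16 mouse ovary libraries, 1 per mouse, from 4 groups of 4: mice on testosterone (On T), mice after testosterone was stopped (Post T), and the age-matched controls of each. Libraries were made per the labels from poly(A) RNA with a directional kit and sequenced as paired ends. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and the genome build GRCm38, without their order. The deposited expected counts are RSEM's estimates per gene made by the authors from the aligned reads, not normalised, and they held whole numbers when checked. The deposited TPM values were scaled by the authors' tool for gene length and library size. Deposited FPKM values were not used here. The annotation release and the use of strand in counting are not stated in the sources used here.

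The expected counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 18833 of 55426, and libraries were scaled by TMM. All 16 libraries entered 1 fit with a mean per group, and contrasts were tested with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The contrasts were On T minus its controls, Post T minus its controls, the difference of these effects, and the older minus the younger controls. The common biological coefficient of variation was 0.179. Standard errors are those implied by the fold change and its F statistic. Levels are counts relative to library size (CPM), scaled by TMM, as the arithmetic mean ± SD of 4 libraries. Principal components used log2 CPM with a prior count of 2.

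Gene lists, 27 in number, were tested with fry in edgeR and limma 3.58.1, where at least 5 members were tested, with adjustment over the lists. The p of fry tests whether the genes of a list move on balance in the same direction, and it does not compare them with other genes. Each list was also tested by limma's camera with an estimated correlation between its members. Camera compares a list with all other genes, so it asks another question than fry. Values given with an estimated correlation are those of camera. Members were also adjusted over the list alone. Some lists share members, so their calls are not separate results. Akr1c18, Star, Cyp11a1 and Hsd17b7 are in the lists of steroidogenesis and of luteal markers, and Star is a periovulatory gene too. Genes raised or lowered on testosterone were tested as sets in the Post T contrast, which shares no library with the On T contrast, with adjustment over the 2 sets.

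Genes were named by a rule. For each treatment contrast it took the 8 largest rises and 8 largest falls among called genes with no overlap between groups and a mean of at least 1 CPM, leaving out predicted and unnamed genes and pseudogenes. It added up to 4 members with the smallest p from each called list, and 12 fixed genes whatever their values. A few genes chosen this way are not reported here. For the difference of effects and for the controls it took 5 genes per direction with the smallest p. Lists, fixed genes, contrasts, tests, this rule and the alternatives were chosen before the data were examined, except where stated otherwise.

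The library totals ranged from 26598055 to 52659637 counts, and 3 counts, taken as the floor, came to 0.0571 to 0.117 CPM in a library. Where a group held 0 counts, a fold is given as a bound against 3 counts over the group, and with 1 count as a ratio with its exact 95% interval. Intervals and floors cover counting error only. Gene positions came from GENCODE for GRCm38, in which 55154 of the identifiers (99.51%) were found. Shared sequence between Myh6 and Myh7 was measured as windows of 150 bases found unchanged in both.

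Alternatives were median-of-ratios size factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0 (Wald test), limma on log2(TPM + 1), a fit of only the 8 libraries compared, a block for the replicate number, age as a covariate, and leaving out each library in turn. Leaving out On T library 2 and Post T control library 1 together was added after seeing the data. The pipeline was also tested on simulated data built from these libraries.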

Results

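Ovaries of 16 female C57BL/6NHsd mice, an inbred strain, were profiled by poly(A) RNA sequencing, with 1 ovary per mouse and 4 mice in each of 4 groups. Mice of the On T group had received 0.9 mg testosterone enanthate, a long-acting testosterone ester, under the skin every week for 6 weeks and were 16 weeks old at collection. In the Post T group the same 6 weeks of injections were stopped and the mice were watched until cycling returned. Their ovaries were taken after 4 further cycles, at 24 to 28 weeks of age. Each treated group had its own controls of matched age that were injected with sesame oil. Every ovary was taken in diestrus, a phase in which corpora lutea are present in cycling mice. Whether the ovaries of the testosterone groups held them was not examined here. The libraries held 29816015 to 45836299 expected counts in the On T controls and 29004008 to 52659637 in the On T group. They held 26598055 to 40442120 in the Post T controls and 30359221 to 44292334 in the Post T group. Of 55426 genes in the table, 18833 had enough counts to be tested. The 4 groups separated on principal components 1 and 2, which held 33.9% and 15.8% of the variance. On component 1 the 8 testosterone libraries lay between 9.65 and 56.2 while the 8 control libraries lay between -54.0 and -18.8.

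**Figure D1:**
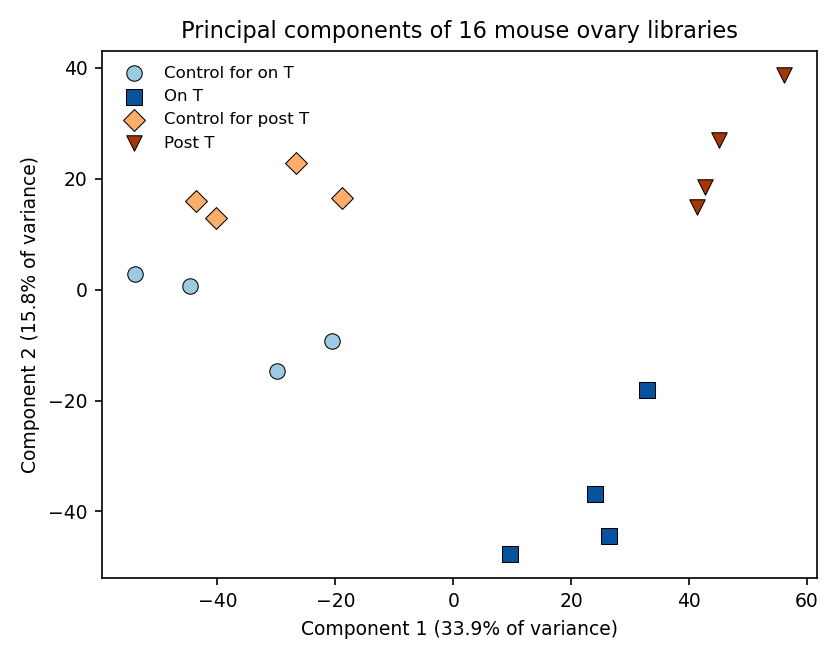
Principal components 1 (x axis, 33.9% of variance) and 2 (y axis, 15.8% of variance) of log2 CPM in the 16 ovary libraries, with each point a library and colour and shape giving its group. The 8 libraries of both testosterone groups lie to the right of 0 and the 8 control libraries to the left, and on component 2 the On T libraries (-47.6 to -18.1) lie below the Post T libraries (14.9 to 38.8).

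The first comparison asked what 6 weeks of testosterone did to the ovary while it was still being given. The largest falls included genes of the corpus luteum, the progesterone-making gland left after ovulation. Akr1c18, which encodes the hydroxysteroid dehydrogenase that inactivates progesterone, averaged 141 ± 35.3 CPM, counts scaled to library size, in controls and 0.643 ± 0.268 on testosterone (SD, n = 4; log2 fold change -7.78, SE 0.26, edgeR adjusted p = 1.54e-11). Ptgfr, the prostaglandin receptor through which luteal regression is signalled, fell from 313 ± 134 to 3.11 ± 2.64 CPM (log2 -6.64, SE 0.51, edgeR adjusted p = 5.42e-07). Sfrp4, a secreted Wnt antagonist, fell from 1144 ± 430 to 5.77 ± 5.06 (log2 -7.63, SE 0.55, edgeR adjusted p = 3.07e-07). In the other direction, Gpnmb, a glycoprotein of lysosome-rich macrophages, rose from 35.2 ± 18.2 to 226 ± 60.0 CPM (log2 2.68, SE 0.34, edgeR adjusted p = 8.52e-05). Myh6, the alpha heavy chain of cardiac myosin, rose from 1.03 ± 0.246 to 65.5 ± 28.4 CPM (log2 5.97, SE 0.45, edgeR adjusted p = 4.11e-07).

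In the table Akr1c18 is ENSMUSG00000021214, and it lies on the minus strand of chromosome 13 at 4132615 to 4150654 of GRCm38. Myh6 (ENSMUSG00000040752, 54941921 to 54966927) and Myh7 (ENSMUSG00000053093, 54970684 to 54994626) are neighbours on the minus strand of chromosome 14, and Gpnmb (ENSMUSG00000029816) lies on the plus strand of chromosome 6 at 49036546 to 49070929. Each of these 4 is annotated as protein-coding, and the values are sums over a gene's exons. Myh6 and Myh7 are close paralogs, and 5.29% of the 150-base windows of Myh6 transcripts occur unchanged in Myh7, so the split of reads between them is uncertain, above all for Myh7.

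Of the 16 luteal marker genes tested, 8 fell and 1 rose on testosterone (10 and 1 when adjusted over the list alone). The list as a whole was lower (fry adjusted p = 0.00033, median log2 fold change -1.12, adjusted p = 0.357 with an estimated correlation). The member that rose was Apoe (log2 0.74, SE 0.21, edgeR adjusted p = 0.0361), a lipid carrier also made by macrophages and named after its values were seen. Of 20 genes of steroidogenesis, 6 fell and 0 rose (8 and 1 adjusted over the list alone, fry adjusted p = 0.0131, adjusted p = 0.903 with an estimated correlation). The median of this list was -0.28 and its mean -0.96. Star, which brings cholesterol into mitochondria, fell by 3.06 on the log2 scale (SE 0.57, edgeR adjusted p = 0.00229). Cyp11a1, which cleaves the cholesterol side chain, fell by 2.09 (SE 0.34, edgeR adjusted p = 0.000864), and Fdxr, which passes electrons to that enzyme, fell by 0.76 (SE 0.14, edgeR adjusted p = 0.00181). Akr1c18, Star, Cyp11a1 and Hsd17b7 (log2 -2.71, edgeR adjusted p = 0.042) are members of the luteal list too, so these list calls are not separate. Leaving out On T library 2 or 4 ended the call of the steroidogenesis list (fry adjusted p = 0.0588 and 0.0569) and moved its median to -0.165 and -0.11. The list means were -1.75 and -1.46 in these 2 libraries and -0.983 and -0.283 in On T libraries 1 and 3, and surface epithelium markers were low in the same 2 (-2.40 and -1.56, against 0.177 and 0.0833). Without On T library 3 or control library 2 the median was -0.70 and -0.45, and it was -0.433 with a block for the replicate number and -0.176 with no filter.

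Of 17 periovulatory genes, which are induced in follicles around ovulation, 8 fell and 0 rose (11 and 1 adjusted over the list alone, fry adjusted p = 0.00145, median log2 -0.74, adjusted p = 0.357 with an estimated correlation). Runx2, a transcription factor of luteinising granulosa cells, fell by 4.43 (SE 0.49, edgeR adjusted p = 2.3e-05). Ereg, an epidermal growth factor-like ligand, fell by 2.92 (SE 0.45, edgeR adjusted p = 0.000585), and Cited2, a transcriptional coregulator, fell by 0.74 (SE 0.13, edgeR adjusted p = 0.00123). Edn2, a contractile peptide, fell by 4.79 (SE 0.88, edgeR adjusted p = 0.00209), with controls between 0.821 and 22.7 CPM. The median of this list was -1.39 without control library 1, -1.32 without On T library 2 and -1.27 without On T library 4. Of 20 immediate early genes, which cells switch on within minutes of a stimulus or of tissue handling, 9 fell and 0 rose (14 and 0 adjusted over the list alone, fry adjusted p = 0.0114, median log2 -0.98, adjusted p = 0.379 with an estimated correlation). Among them Egr3 fell by 2.80 (SE 0.53, edgeR adjusted p = 0.00267), Ier3 by 2.05 (SE 0.28, edgeR adjusted p = 0.000186), Junb by 1.44 (SE 0.25, edgeR adjusted p = 0.00142) and Jun by 0.97 (SE 0.15, edgeR adjusted p = 0.000464).

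Of 25 genes of lysosomes and multinucleated macrophages, 8 rose and 0 fell (10 and 0 adjusted over the list alone, fry adjusted p = 0.0262, median log2 0.31, adjusted p = 0.803 with an estimated correlation). Mmp12, the macrophage elastase, rose by 2.05 (SE 0.30, edgeR adjusted p = 0.00032). Atp6v0d2, a subunit of the proton pump of lysosomes and osteoclasts, rose by 1.78 (SE 0.25, edgeR adjusted p = 0.000282), and Itgax, an integrin of dendritic cells and macrophages, by 1.49 (SE 0.19, edgeR adjusted p = 0.000123). This call ended without control library 2 or 4 or On T library 1, 2 or 4 (fry adjusted p = 0.0897, 0.1, 0.0773, 0.0576 and 0.0748) and with a block for the replicate number (fry adjusted p = 0.051). In a fit of the 8 libraries compared alone, the luteal list remained called, and the other 4 lists had fry adjusted p from 0.0651 to 0.103. Macrophage markers as a list were not called on testosterone (6 rose and 1 fell of 24, 8 and 1 adjusted over the list alone, fry adjusted p = 0.494). Adgre1, a surface receptor of macrophages, was at 14.4 ± 1.76 CPM in controls and 14.6 ± 3.93 on testosterone (log2 0.03, SE 0.20, edgeR adjusted p = 0.958).

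Among the largest falls outside these lists were Wnt10b (log2 -8.49, SE 0.49) and Wnt7b (log2 -6.59, SE 0.63), both secreted Wnt ligands, and Onecut2, a homeobox transcription factor (log2 -7.98, SE 0.27). Plekhg4, a guanine nucleotide exchange factor (log2 -7.47, SE 0.52), and Saa2, an acute-phase apolipoprotein (log2 -6.51, SE 0.80), fell too, and the edgeR adjusted p of these 5 lay between 1.54e-11 and 0.000186. The largest rises besides Myh6 were Sfrp5, a Wnt antagonist (log2 3.45, SE 0.54), Myh7, the beta heavy chain of cardiac myosin (log2 3.22, SE 0.25), the glutathione transferase gene Gsta2 (log2 3.11, SE 0.33), and Pdia2, a protein disulfide isomerase (log2 3.07, SE 0.26). They were followed by Mcoln3, an ion channel of endosomes and lysosomes (log2 2.91, SE 0.40), Awat1, a wax ester synthase (log2 2.75, SE 0.53), and the lysozyme gene Lyz1 (log2 2.74, SE 0.40). The edgeR adjusted p of these 7 lay between 4.52e-07 and 0.00314. Awat1 and Sfrp5 averaged 0.0346 and 0.0630 CPM in controls, and Onecut2 and Saa2 averaged 0.0668 and 0.0573 CPM on testosterone, so the sizes of these changes rest on few counts. Saa2, Gsta2 and Lyz1 belong to families of similar genes and are uncertain where reads were shared. On the log2(TPM + 1) scale, which understates changes of low genes, the rise of Awat1 was 0.34 (limma adjusted p = 0.0893), and those of Sfrp5, Mcoln3, Lyz1 and Myh7 were 0.59, 0.75, 1.12 and 2.10. The falls of Onecut2, Saa2, Wnt7b, Wnt10b, Ereg, Egr3 and Edn2 were -1.28, -3.69, -3.78, -5.35, -0.54, -1.55 and -2.33 on that scale.

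Several receptor and follicle genes chosen beforehand did not pass the test on testosterone. The estrogen receptor Esr1 (log2 0.16, SE 0.22), the follicle-stimulating hormone receptor Fshr (log2 -0.22, SE 0.30), the aromatase gene Cyp19a1 (log2 -0.37, SE 0.63), the androgen-making enzyme gene Cyp17a1 (log2 -0.14, SE 0.92) and the oocyte factor Gdf9 (log2 -0.33, SE 0.18) had edgeR adjusted p between 0.301 and 0.952. Amh, made by granulosa cells of growing follicles, had a log2 fold change of 0.46 (SE 0.22, edgeR adjusted p = 0.217), and without On T library 2 it passed (log2 0.65; adjusted p = 0.0362). Lhcgr, the luteinising hormone receptor, had a log2 fold change of -1.46 (SE 0.51, edgeR adjusted p = 0.0858), and it passed without On T library 3 (log2 -1.94; adjusted p = 0.0296) and in the fit of the 8 libraries alone (adjusted p = 0.0339).

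In all, 1746 of the 18833 genes differed on testosterone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 799 were higher and 947 lower. More than 2-fold changes made up 236 of the higher and 443 of the lower genes. The 4 treated and 4 control libraries did not overlap for 15.1% of the genes, where chance gives 2.86%. The count was 1081 without control library 4 (478 higher), 1094 without control library 2 (470 higher) and 1130 with limma on log2(TPM + 1) (490 higher). DESeq2 called 2346, of which 1192 were higher and 1154 lower, and without On T library 3 more genes were higher (946) than lower (818).

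**Figure D2:**
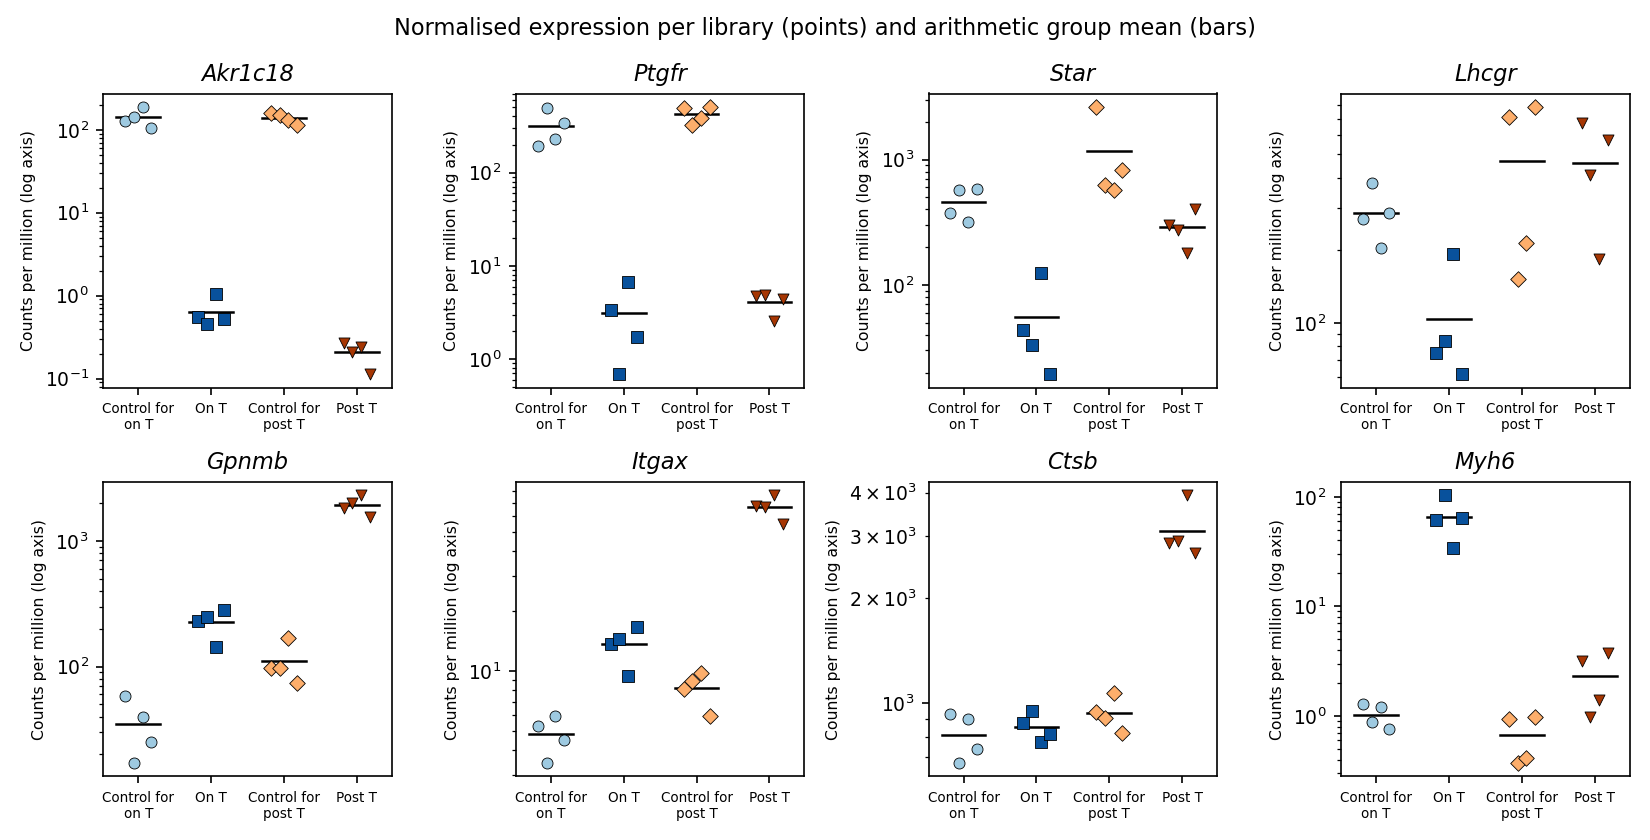
Normalised expression of 8 genes (CPM, log axis) in each of the 16 libraries, by group; points are libraries and bars are arithmetic means of 4. Akr1c18 and Ptgfr lie far below controls in both testosterone groups, Gpnmb and Itgax lie above controls in both and highest post testosterone, Ctsb lies above controls post testosterone (3104 ± 560 against 934 ± 103, SD), Myh6 lies highest on testosterone (65.5 ± 28.4, SD), and Lhcgr overlaps between the Post T group and its controls.

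The second comparison asked what remained different in the ovary after testosterone had been stopped and cycles had returned. The luteal genes with the largest falls on testosterone were low here too. Akr1c18 averaged 139 ± 21.0 CPM in controls and 0.207 ± 0.0679 post testosterone (SD, n = 4; log2 fold change -9.39, SE 0.29, edgeR adjusted p = 5.92e-12). Ptgfr was at 429 ± 87.5 and 4.12 ± 1.06 (log2 -6.69, SE 0.51, edgeR adjusted p = 2.38e-07), and Sfrp4 at 1132 ± 301 and 25.4 ± 8.34 (log2 -5.48, SE 0.50, edgeR adjusted p = 9.82e-07). Genes of lysosome-rich macrophages were higher. Gpnmb rose from 110 ± 40.9 to 1917 ± 313 CPM (log2 4.12, SE 0.36, edgeR adjusted p = 7e-07), and Ctsb, the lysosomal protease cathepsin B, from 934 ± 103 to 3104 ± 560 (log2 1.73, SE 0.14, edgeR adjusted p = 3.18e-07). On the opposite strand, 12.8% of the exon bases of Ctsb overlap Fdft1, and whether counting used the strand is not stated.

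Of 25 genes of lysosomes and multinucleated macrophages, 21 rose and 0 fell post testosterone (21 and 0 adjusted over the list alone, fry adjusted p = 5.44e-06, median log2 1.60, adjusted p = 0.0886 with an estimated correlation). Itgax rose by 3.02 (SE 0.20, edgeR adjusted p = 6.54e-08), Fabp5, a fatty acid carrier, by 2.57 (SE 0.17, edgeR adjusted p = 8.33e-08), and Lipa, the acid lipase of lysosomes, by 1.60 (SE 0.13, edgeR adjusted p = 3.35e-07). Of 24 macrophage markers, 15 rose and 2 fell (18 and 2 adjusted over the list alone, fry adjusted p = 0.000718, median log2 1.01, adjusted p = 0.24 with an estimated correlation). The risers included Cd68, a lysosomal membrane protein (log2 2.61, SE 0.23), the lysosomal protease gene Ctss (log2 2.74, SE 0.26), Tyrobp, a signalling adaptor of myeloid receptors (log2 2.48, SE 0.23), and Laptm5, a lysosomal membrane protein of blood cells (log2 2.34, SE 0.20), with edgeR adjusted p between 5.68e-07 and 1.98e-06. The 2 members that fell, named after their values were seen, were the chemokine receptor gene Cx3cr1 (log2 -0.86, SE 0.18, edgeR adjusted p = 0.00374) and the scavenger receptor gene Cd163 (log2 -1.92, SE 0.53, edgeR adjusted p = 0.0246). Adgre1 was at 16.0 ± 4.90 CPM in controls and 22.6 ± 0.542 post testosterone and did not pass (log2 0.50, SE 0.20, edgeR adjusted p = 0.121), although it passed without control library 3 (log2 0.76; adjusted p = 0.00865).

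Other immune lists were higher too. Of 25 cytokine and chemokine genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone, fry adjusted p = 0.00344, median log2 1.11, adjusted p = 0.279 with an estimated correlation). Among them were the interleukin gene Il1a (log2 3.15, SE 0.29) and the chemokine genes Ccl3 (log2 2.66, SE 0.45), Ccl5 (log2 1.55, SE 0.26) and Cxcl10 (log2 1.52, SE 0.23), with edgeR adjusted p between 1.31e-06 and 0.000572. The member that fell, named after its value was seen, was Il34, a ligand of the macrophage growth factor receptor (log2 -1.15, SE 0.20, edgeR adjusted p = 0.000804). Of 21 lymphocyte markers, 10 rose and 0 fell (11 and 0 adjusted over the list alone, fry adjusted p = 0.000721, median log2 1.00, adjusted p = 0.24 with an estimated correlation). The risers included Il7r, an interleukin receptor of lymphocytes, at 3.01 (SE 0.27), Cd4, the co-receptor of helper T cells, at 2.49 (SE 0.33), Ptprc, the pan-leukocyte phosphatase, at 1.56 (SE 0.15) and Trbc2, a constant segment of the T-cell receptor, at 1.00 (SE 0.18), all with edgeR adjusted p of 0.000807 or lower. Trbc2 has a near-identical partner segment and is uncertain. Of 17 antigen presentation genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, fry adjusted p = 0.00159, median log2 0.495, adjusted p = 0.24 with an estimated correlation). The class I genes H2-D1 (log2 1.60, SE 0.16) and H2-K1 (log2 0.74, SE 0.12), which share reads with related genes and are uncertain, were among them. B2m, the light chain of class I molecules (log2 1.10, SE 0.12), and the immunoproteasome subunit gene Psmb8 (log2 0.86, SE 0.11) rose too, with edgeR adjusted p of the 4 between 2.75e-06 and 0.000334.

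Genes encoded by the mitochondrial genome were also higher as a list, with 2 risers and 0 that fell of 13 (9 and 0 adjusted over the list alone, fry adjusted p = 0.0363, median log2 0.39, adjusted p = 0.465 with an estimated correlation). The respiratory chain genes mt-Co1 (log2 0.44, SE 0.11, edgeR adjusted p = 0.0119) and mt-Nd5 (log2 0.41, SE 0.12, edgeR adjusted p = 0.0272) rose. The genes mt-Nd1 (log2 0.40, SE 0.14, edgeR adjusted p = 0.0737) and mt-Nd4 (log2 0.40, SE 0.13, edgeR adjusted p = 0.0636) did not pass. These genes took 2.33% to 3.04% of the counts in the 4 Post T libraries and 1.90% to 2.21% in their 4 controls. The list call ended without any of 6 libraries, namely each of the 4 controls and Post T libraries 2 and 3 (fry adjusted p = 0.0724, 0.0501, 0.104, 0.0573, 0.0691 and 0.147). That of mt-Nd5 ended without control library 1 or 3 or Post T library 2 or 3 (adjusted p = 0.0578, 0.0587, 0.064 and 0.0554) and in the fit of the 8 libraries alone (adjusted p = 0.0622). In DESeq2 mt-Nd1 and mt-Nd4 passed (adjusted p = 0.0461 and 0.0337), and mt-Nd4 passed without Post T library 1 (adjusted p = 0.0409). With limma on log2(TPM + 1), mt-Co1 and mt-Nd5 did not pass (adjusted p = 0.0619 and 0.123).

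Of the 16 luteal markers, 8 fell and 2 rose post testosterone (10 and 2 adjusted over the list alone, fry adjusted p = 0.000898, median log2 -0.94, adjusted p = 0.24 with an estimated correlation). Rgcc, a cell cycle regulator of luteal and endothelial cells, fell by 1.76 (SE 0.27, edgeR adjusted p = 0.000229). The members that rose, named after their values were seen, were the lipid genes Apoe (log2 1.38, SE 0.21, edgeR adjusted p = 0.000246) and Abca1 (log2 0.83, SE 0.16, edgeR adjusted p = 0.00194), both also expressed by macrophages. Of 20 genes of steroidogenesis, 4 fell and 0 rose (5 and 0 adjusted over the list alone, fry adjusted p = 0.0363, median log2 -0.22, adjusted p = 0.774 with an estimated correlation). Hsd17b7, an enzyme of estradiol and cholesterol synthesis, fell by 4.02 (SE 0.84, edgeR adjusted p = 0.00357), Star by 2.01 (SE 0.54, edgeR adjusted p = 0.0204) and Fdxr by 0.55 (SE 0.14, edgeR adjusted p = 0.012). Hsd17b7 was spread widely in controls, at 644 ± 566 CPM against 39.55 ± 14.2 post testosterone (SD). Akr1c18, Hsd17b7 and Star are also in the luteal list, which leaves Fdxr as the only called faller outside it. The steroidogenesis call ended without control library 1, 3 or 4 or Post T library 1, 2 or 3 (fry adjusted p = 0.0883, 0.0576, 0.0714, 0.0521, 0.12 and 0.168). The median was -0.05, -0.14 and -0.13 without control library 1 and Post T libraries 2 and 3.

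Control library 1 held 2630 CPM of Star against 574 to 824 in the other 3 controls, and without it the change of Star was -1.20 (edgeR adjusted p = 0.112) and that of Fdxr was -0.36 (adjusted p = 0.0471). The call of Star also ended without Post T library 1, 2 or 3 (adjusted p = 0.0528, 0.057 and 0.0709), with limma on log2(TPM + 1) (adjusted p = 0.0598) and with a block for the replicate number (-1.86; adjusted p = 0.0544), and that of Fdxr ended without Post T library 1 (adjusted p = 0.0611).

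Of 17 periovulatory genes, 3 fell and 0 rose (9 and 0 adjusted over the list alone, fry adjusted p = 0.00284, median log2 -0.52, adjusted p = 0.24 with an estimated correlation). They were Runx2 (log2 -4.65, SE 0.48, edgeR adjusted p = 4.22e-06), Cited2 (log2 -0.54, SE 0.13, edgeR adjusted p = 0.00776) and Star. Has2, which makes the hyaluronan of the expanding cumulus, had a log2 fold change of -1.63 (SE 0.56, edgeR adjusted p = 0.069), with adjusted p of 0.0314 in DESeq2, 0.0206 in the fit of the 8 libraries alone and 0.00671 with a block for the replicate number. Markers of oviduct epithelium, a neighbouring tissue, were lower as a list, although 2 fell and 1 rose of 11 (2 and 1 adjusted over the list alone, fry adjusted p = 0.0202, median log2 -0.70, adjusted p = 0.279 with an estimated correlation). The cilia genes Rsph1 (log2 -1.51, SE 0.26, edgeR adjusted p = 0.000638) and Dnah9 (log2 -0.70, SE 0.22, edgeR adjusted p = 0.0465) fell. Tppp3, a tubulin-binding protein, rose by 0.67 (SE 0.17, edgeR adjusted p = 0.0139), and the cilia gene Dnah5 did not pass (log2 -1.59, SE 0.76, edgeR adjusted p = 0.22). The oviduct list lost its call with no filter, with a stricter filter, where its median was -0.09, and without any of the 4 controls or Post T libraries 1, 3 and 4 (fry adjusted p from 0.0714 to 0.168). Dnah9 lost its call with limma (adjusted p = 0.459), with no filter (0.0934), with the stricter filter (0.0533), in the fit of 8 libraries (0.0748) and with age in the model (0.056). It also did without control library 2, 3 or 4 or Post T library 1, 3 or 4 (adjusted p = 0.155, 0.0799, 0.106, 0.122, 0.126 and 0.123).

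The largest rises outside those described above were Sfrp5 (log2 5.89, SE 0.42), Cxcr1, a chemokine receptor of neutrophils (log2 4.78, SE 0.41), Mcoln3 (log2 4.42, SE 0.35) and Awat1 (log2 4.34, SE 0.36). Clec4e, a myeloid receptor for microbial and self lipids (log2 4.26, SE 0.49), Clca3a2, of a family of calcium-activated chloride channel regulators (log2 4.22, SE 0.42), and Pira2, a paired immunoglobulin-like receptor of myeloid cells (log2 3.92, SE 0.26), rose as well, and the edgeR adjusted p of these 7 lay between 6.54e-08 and 1.05e-05. Pira2 and Clca3a2 sit in families of near-identical copies and are uncertain. Among the falls, Wnt10b (log2 -9.12, SE 0.50) and Onecut2 (log2 -7.67, SE 0.27) were low again (edgeR adjusted p = 8.25e-09 and 1.99e-11). Saa2 had 0 counts in the 4 Post T libraries and 1015 in their controls, which makes it at least 379-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 1.68e-05). S100g, a calcium-binding protein, had 0 against 211 counts and was at least 78.8-fold lower against the same floor (edgeR adjusted p = 0.00822). Bpifb6, of a family of lipid-binding proteins, had 1 count against 392, a ratio of 439 with a 95% exact counting interval from 78.4 to 17400 (edgeR adjusted p = 0.000898). Its controls were spread widely (3.35 ± 4.13 CPM, SD), which that interval does not cover.

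Ces2a, a carboxylesterase of a multigene family and therefore uncertain (log2 -9.18, SE 1.69, edgeR adjusted p = 0.00122), and Bhmt, a betaine methyltransferase (log2 -7.67, SE 1.68, edgeR adjusted p = 0.00508), also fell. Their controls were spread widely, from 0.874 to 86.3 CPM for Ces2a and from 0.437 to 183 for Bhmt. Ces2a and Onecut2 averaged 0.0541 and 0.0850 CPM post testosterone, so the sizes of these falls rest on few counts. Bhmt did not pass with limma on log2(TPM + 1) (-3.06; adjusted p = 0.0544). On that scale the rises of Sfrp5, Cxcr1, Mcoln3, Awat1, Clec4e, Clca3a2 and Il1a were 3.34, 2.62, 2.58, 2.15, 1.32, 0.99 and 1.98, and the falls of Wnt10b, Onecut2, Saa2, S100g, Bpifb6 and Ces2a were -5.77, -1.26, -4.55, -2.85, -1.59 and -3.63.

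These genes did not pass post testosterone either. Esr1 (log2 -0.33, SE 0.22), Fshr (log2 0.03, SE 0.31), Cyp19a1 (log2 0.32, SE 0.64), Cyp17a1 (log2 1.79, SE 0.95), Amh (log2 -0.10, SE 0.22) and Gdf9 (log2 0.09, SE 0.18) had edgeR adjusted p between 0.284 and 0.97. Lhcgr was at 467 ± 330 CPM in controls and 461 ± 213 post testosterone (log2 -0.02, SE 0.49, edgeR adjusted p = 0.99).

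In all, 2315 genes differed post testosterone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 1410 were higher and 905 lower, and 676 and 441 of these changed by more than 2-fold. The groups did not overlap for 16.5% of the genes, where chance gives 2.86%.

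**Figure D3:**
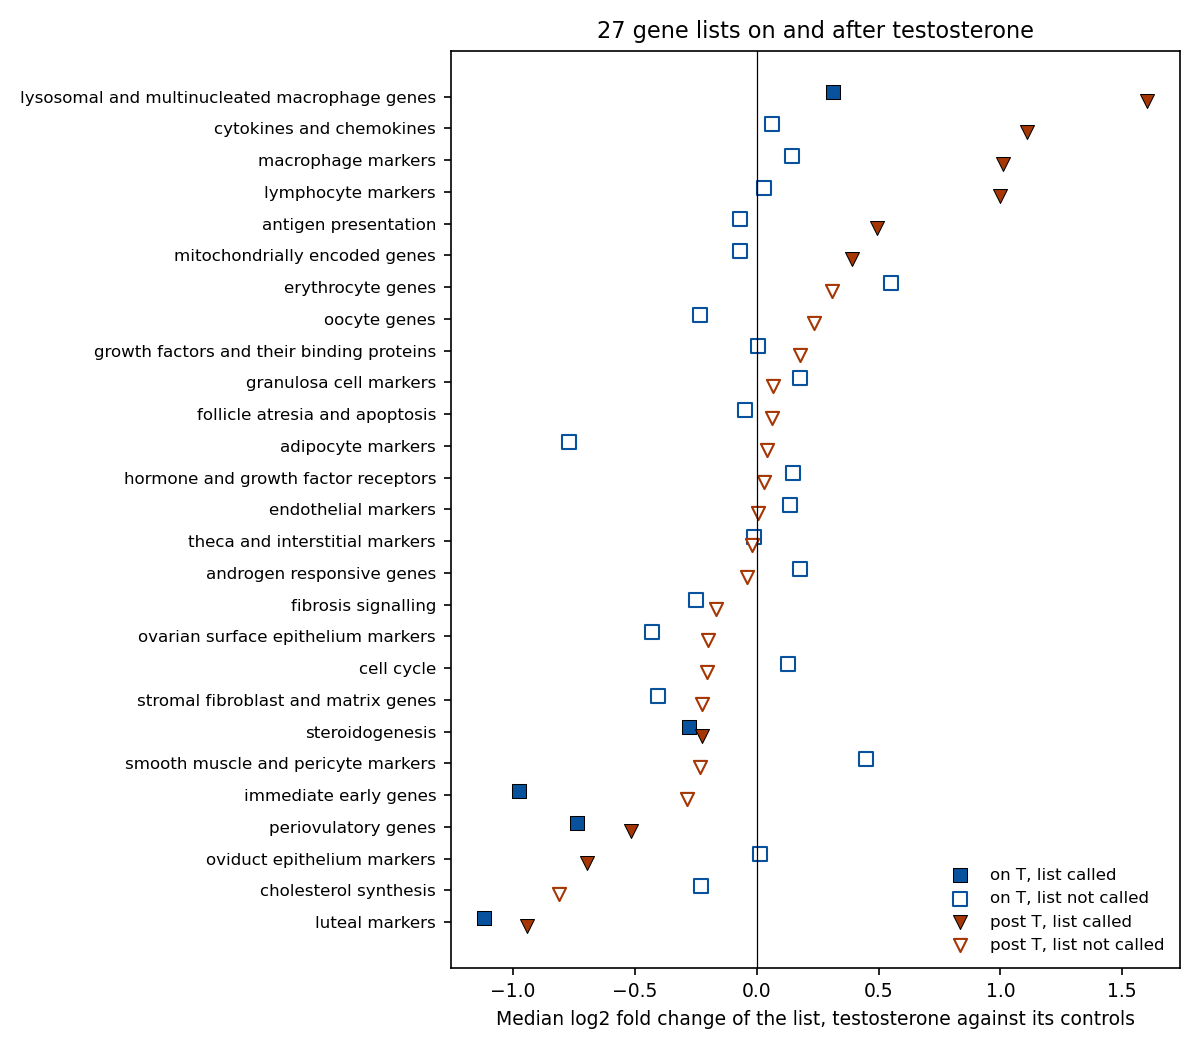
Median log2 fold change (x axis) of each of the 27 gene lists (y axis) on testosterone (squares) and post testosterone (triangles), each against its own controls; filled symbols mark lists with a fry adjusted p under 0.05. The 5 lists called on testosterone lie at -1.12 to 0.31 and the 10 called post testosterone at -0.94 to 1.60. By camera with an estimated correlation, which compares a list with other genes, 0 lists were called in either comparison.

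The 2 sets of changes were then set against each other. They come from separate mice and share no library. They do share 1 fit and its estimates of spread, and the expected numbers take all genes as equally easy to call. The excess over these numbers is therefore overstated to an unknown degree. Of the 799 genes raised on testosterone, 332 were also raised post testosterone, where 59.8 are expected from independent lists, and 3 were lower. Of the 947 lowered on testosterone, 434 were also lowered, where 45.5 are expected, and 18 were higher. The raised genes had a median log2 fold change of 0.76 on testosterone and 0.41 post testosterone, with 88.0% on the same side of 0 (fry adjusted p = 6.43e-06 over both sets). The lowered genes had medians of -0.94 and -0.53 with 84.3% on the same side (fry adjusted p = 2.81e-06 over both sets). As the sets were chosen by passing on testosterone, their medians there are inflated by that choice. The smaller medians post testosterone therefore do not by themselves show recovery. Across the 18833 genes, which are not independent replicates, the fold changes had a Pearson r of 0.613.

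**Figure D4:**
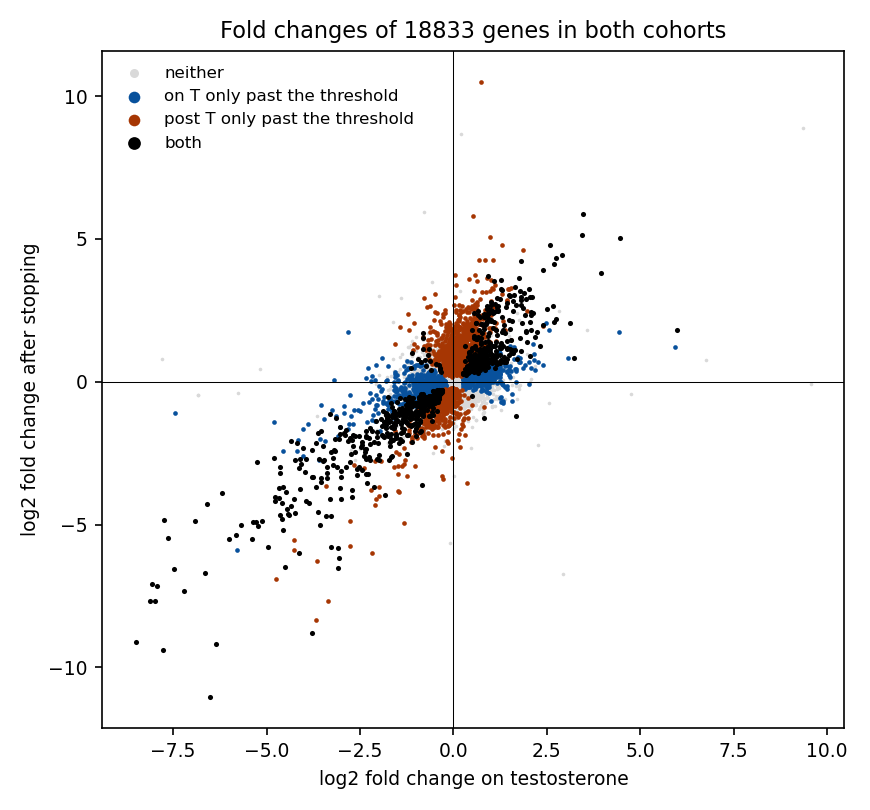
Fitted log2 fold change on testosterone (x axis) against that post testosterone (y axis) for 18833 genes, coloured by which of the comparisons passed an adjusted p of 0.05. Points past the threshold in both lie mostly in the lower left (434 genes) and the upper right (332 genes); fitted values of genes with 0 counts in a group, such as Saa2, are not bounds.

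The third comparison tested the difference between the effects directly, as the effect on testosterone minus that after stopping. The cohorts also differed in age and in time since the first injection, which cannot be told apart from the stopping of testosterone. Ctsb did not pass on testosterone (log2 0.07) and rose by 1.73 after stopping, a difference of -1.66 (SE 0.19, edgeR adjusted p = 0.000508). Cd44, a hyaluronan receptor, fell by 0.82 on testosterone and rose by 1.54 after stopping, a difference of -2.36 (SE 0.26, edgeR adjusted p = 0.000508). Cdkn1c, an imprinted inhibitor of cell division, rose in both cohorts, by 0.91 and 3.69, and differed by -2.77 (SE 0.31, edgeR adjusted p = 0.000508). Tnfaip2, a gene induced by tumour necrosis factor, rose by 1.66 after stopping and differed by -1.69 (SE 0.18, edgeR adjusted p = 0.000508).

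Of the 27 lists, 6 differed between the cohorts. The effect on testosterone was the lower for the lysosomal list (13 of 25 members, 20 adjusted over the list alone, fry adjusted p = 0.00466, median difference -1.17). So it was for macrophage markers (9 of 24, 16 adjusted over the list alone, fry adjusted p = 0.0207, median -0.94) and antigen presentation (4 of 17, 7 adjusted over the list alone, fry adjusted p = 0.0207, median -0.56). Cytokines and chemokines (8 of 25, 12 adjusted over the list alone, fry adjusted p = 0.0207, median -1.26) and lymphocyte markers (3 of 21, 4 adjusted over the list alone, fry adjusted p = 0.0353, median -0.58) had the same direction. It was the higher for oviduct markers, of which 0 of 11 members passed (0 adjusted over the list alone, fry adjusted p = 0.0381, median difference 0.59). With an estimated correlation these adjusted p were 0.349 for lymphocyte markers, and the other 5 lists had adjusted p = 0.267 with an estimated correlation. The luteal list did not pass this test (median -0.03; fry adjusted p = 0.746; 0 of 16 members passed, and 3 adjusted over the list alone).

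Genes with the larger rise on testosterone included Myh6 (difference 4.16, SE 0.65, edgeR adjusted p = 0.00158), Myh7 (2.40, SE 0.35, edgeR adjusted p = 0.00101) and Pdia2 (2.26, SE 0.37, edgeR adjusted p = 0.0019). Myh6 and Myh7 were higher post testosterone as well, by 1.81 and 0.82 (edgeR adjusted p = 0.0161 and 0.0423), while Pdia2 did not pass there (log2 0.81, edgeR adjusted p = 0.054). Snap91, a clathrin adaptor of synapses, fell by 0.84 on testosterone and fell by 3.60 after stopping (difference 2.77, SE 0.37, edgeR adjusted p = 0.000676). Gabrb1, a subunit of the receptor for gamma-aminobutyric acid, rose by 0.82 and fell by 1.26 (difference 2.08, SE 0.34, edgeR adjusted p = 0.00216). Its difference on the log2(TPM + 1) scale was 0.31 (limma adjusted p = 0.138), and that of Snap91 was 1.28. In all, 612 genes differed between the cohorts, 61 with a positive and 551 with a negative difference, and DESeq2 called 999, 216 of them positive. The positive ones numbered 32 without On T library 1 or 4, and 31 and 34 without Post T library 1 and 4. They numbered 37, 40 and 35 without library 1, 3 and 4 of the younger controls, 39 with no filter, and 93 without On T library 2 and library 1 of the older controls together.

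The control groups, which differed in age and cohort, were compared as the background of these results. By edgeR 0 genes passed (smallest adjusted p = 0.0682; 1892 at an unadjusted p under 0.05), DESeq2 called 173 genes, limma on log2(TPM + 1) called 0, and edgeR without a filter called 20. Leaving out library 1 or 4 of the younger controls gave 9 and 1 genes, and leaving out library 1, 2 or 4 of the older controls gave 1, 4 and 1. By fry 0 of the 27 lists passed, and 0 with an estimated correlation, with the smallest fry adjusted p at 0.169 for oocyte genes (median log2 -0.58, older against younger; 22 of 30 lower when adjusted over the list alone) and lymphocyte markers (median log2 0.39).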

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

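The tests of the luteal and macrophage patterns and the counts of other splits were chosen only after the results were seen, while the 3 tests of Myh6 and Myh7 were set before their results were seen.

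Of 16 luteal markers, 8 were called lower in each cohort and 1 and 2 higher, while the list had adjusted p = 0.357 and 0.24 with an estimated correlation. A loss of luteal tissue as a whole may underlie the pattern, but 8 of the 16 members were not called lower after stopping. It stays open, because members such as Hsd3b1 and Nr5a2 are also made by other ovarian cells. A lower transcription of some luteal genes without a loss of tissue stays open as the biological explanation and was not tested.

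After testosterone was stopped, 15 of 24 macrophage markers, 21 of 25 lysosomal genes and 10 of 21 lymphocyte markers were called higher and 2, 0 and 0 lower, in groups matched for age (mean 26 weeks in both), while the lists had adjusted p = 0.24, 0.0886 and 0.24 with an estimated correlation. Blood left in the tissue stays open for all 3 lists. Their mean changes lay above that of erythrocyte genes by 1.48 (SE 0.624) for lysosomal genes, 1.00 (SE 0.664) for macrophage markers and 0.627 (SE 0.542) for lymphocyte markers. The first gap passed the bar of 2 standard errors, but narrowly for 4 libraries per group, and the others did not. The mean change of the 6 erythrocyte genes itself had an SE of 0.58, too wide to decide. A lower share of the main ovarian cells that raises all minor cell types alike is argued against by endothelial markers. Their mean change lay below those of the lysosomal, macrophage and lymphocyte lists by 1.48 (SE 0.109), 1.00 (SE 0.129) and 0.63 (SE 0.126). A loss of main cells that also took endothelial cells stays open, since these markers cannot decide it. The mitochondrial share of counts was higher in the same libraries (2.33% to 3.04% against 1.90% to 2.21%), and a part of tissue or library quality in the rise stays open. More macrophages, or more lysosomal transcripts in each, stay open too and were not told apart.

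Myh6 and Myh7 were higher on testosterone and, by less, after stopping, and the rise on testosterone was examined. Cardiac muscle in the libraries is argued against by a median log2 change of 0.293 over the 11 tested of 18 cardiac genes (-0.86 to 2.27), of which Casq2, Tnnt2 and Tnni3 were called higher. A change of the chromosomal region is argued against, since 0 of 16 other tested genes within 200 kb were called higher (highest log2 0.83) and 2 were called lower. Reads of Myh6 counted as Myh7 could give a gain of 3.41 CPM by shared windows, below the gain of Myh7 of 7.65 (SE 1.14), so they leave the rise of Myh7 uncertain in size. Which cells carry the rise was not tested.

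Chance in the grouping was examined with other splits of the same libraries. For genes changed on testosterone, 1 of 35 splits, the real one, gave as many as 1746, and the highest other gave 15. After stopping, 1 of 35 gave as many as 2315, and the highest other gave 1. For lists, 1 of 35 splits gave as many as 5 on testosterone (highest other 4), 1 of 35 gave as many as 10 after stopping (highest other 1), and 1 of 100 gave as many as 6 for the difference (highest other 5). For the medians after stopping, 1 of 35 reached 0.414 for raised genes (highest other 0.295) and 1 of 35 reached -0.534 for lowered genes (highest other -0.278). The gene counts and the medians argue against chance only as far as such splits can, since 1 of 35 is the smallest share possible. For the lists chance is not excluded, since the counts on testosterone and for the difference led by 1 list. By camera with an estimated correlation, which compares a list with other genes, 0 lists were called. For the difference of effects, 3 of 100 splits reached 612 genes. The others, with 1055 and 1826, kept 3 of the 4 On T labels and 0 of the 4 Post T labels, so they add the effects rather than subtract them, which is a structure of the samples. The same splits gave 4 and 5 lists. Shuffling within each cohort models no effect in either rather than equal effects, so these splits do not decide whether the effects differ. For the controls the real count was 0, which 35 of 35 splits reach by definition, so the splits decide nothing there. The highest other gave 182.

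A library lay far from the other 3 of its group, by Dixon's test of the gap over the range, in 7 of 202 gene and group pairs (3.47%) and in 9 of 108 list and group pairs, where chance gives about 1 in 20. Among genes these were Adgre1 in Post T control 3, highest (0.897), Ptgfr in Post T 3, lowest (0.858), Pdia2 in On T 3, lowest (0.851), Fdxr in On T control 1, highest (0.874), Bpifb6 in Post T 1, highest (1), Clec4e in Post T 2, highest (0.91), and Ccl5 in Post T control 3, lowest (0.876). Among list means, steroidogenesis was highest in On T control 4 (0.865), and stromal and fibrosis genes were lowest in Post T control 1 (0.872 and 0.905). Lysosomal genes were lowest and cholesterol synthesis genes highest in On T 3 (0.935 and 0.882), and androgen responsive genes and adipocyte markers were highest in On T 2 (0.853 and 0.985). Hormone receptors were lowest in Post T 3 (0.924), and adipocyte markers were highest in Post T 2 (0.859).

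The effects of the cohorts differed by the test of the difference, on testosterone minus after stopping in log2, for 29 genes that are reported here and were named by the rule. Among these the difference was negative for 24. Macrophage and lysosomal genes were Atp6v0d2 (-1.39), Cd68 (-1.44), Ctsb (-1.66), Fabp5 (-1.65), Itgax (-1.53), Laptm5 (-1.69), Lipa (-1.29) and Tyrobp (-1.45). Genes of cytokines, lymphocytes and antigen presentation were Ccl3 (-2.44), Cxcl10 (-1.46), Il1a (-2.38), Il7r (-1.48), Ptprc (-1.315), Trbc2 (-0.97), B2m (-0.81), H2-D1 (-1.06) and Psmb8 (-0.89). The others were Cd44 (-2.355), Cdkn1c (-2.77), Clca3a2 (-2.42), Clec4e (-3.41), Jun (-1.02), Pira2 (-1.525) and Tnfaip2 (-1.69). It was positive for Gabrb1 (2.08), Myh6 (4.16), Myh7 (2.40), Pdia2 (2.26) and Snap91 (2.77). List medians differed by -0.943 for macrophage markers, -1.17 for lysosomal genes, -0.562 for antigen presentation, -0.578 for lymphocyte markers, -1.26 for cytokines and 0.59 for oviduct markers, while with an estimated correlation the adjusted p was 0.349 for lymphocyte markers and 0.267 for the other 5 lists.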

How the results depend on the processing

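The alternative without On T library 2 and Post T control library 1 was chosen after seeing the data, as these lay farthest out on components 3 (-49.0) and 4 (-51.5). Genes changed after stopping numbered 1860 to 2801 over the alternatives and 1753 to 2294 without 1 library, and 0 genes called in both an alternative and the main setting had opposite directions. Genes changed on testosterone numbered 1130 with limma on log2(TPM + 1), 2346 in DESeq2 and 1081 to 1764 without 1 library. More of them were higher than lower in DESeq2 (1192 and 1154) and without On T library 3 (946 and 818). Genes whose effects differed numbered 999 in DESeq2. Genes differing between controls numbered 20 with no filter, 173 in DESeq2, 1 without the 2 libraries and 0 to 9 without 1 library. Lists called on testosterone numbered 1 in the fit of the 8 libraries compared, 0 with an estimated correlation and 3 to 7 without 1 library. Lists called after stopping numbered 0 with an estimated correlation. The medians after stopping were 0.329 to 0.519 for genes raised and -0.734 to -0.479 for genes lowered on testosterone without 1 library. With a block for the replicate number 1676 genes were called on testosterone (1545 shared) and 2274 after stopping (2126 shared). The numbers did not pair the libraries, since the correlation of equal numbers was -0.019 to 0.13 and 0.042 to 0.23 in the cohorts. Every value that changed sign belonged to a gene that did not pass the test. After stopping, Fshr was -0.0459 with limma, and Lhcgr was 0.0455 with the block, 0.0103 with age and 0.278 without the 2 libraries. On testosterone without the 2 libraries, Adgre1 was -0.107, Cyp17a1 0.183, Cyp19a1 0.00515, Esr1 -0.000325 and Fshr 0.0438. Without 1 library the ranges on testosterone were -2.11 to 0.230 for Cyp17a1, -0.110 to 0.198 for Adgre1, -0.972 to 0.000890 for Cyp19a1, -0.00375 to 0.313 for Esr1 and -0.476 to 0.0386 for Fshr. After stopping they were -0.303 to 0.351 for Lhcgr, -0.122 to 0.212 for Fshr, -0.00360 to 0.167 for Gdf9 and -0.149 to 0.000106 for Amh. With camera the test itself differs, and with fewer libraries the spread is estimated from fewer samples, while for the other changes the cause was not tested. Without the 2 libraries the calls of Star after stopping (-1.20; adjusted p = 0.0976), lysosomal genes on testosterone (median 0.309; fry adjusted p = 0.0678) and steroidogenesis on testosterone and after stopping (medians -0.159 and -0.0537; fry adjusted p = 0.0501 and 0.0848) ended, while Amh on testosterone (0.656; adjusted p = 0.0301) and mt-Nd1 after stopping (0.456; adjusted p = 0.0193) passed. Depth limits genes near the floor of 3 counts, such as Awat1 and Sfrp5 in the younger controls.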

Other observations

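Genes in this part outside the naming rule were chosen after their values were seen. Cholesterol synthesis genes were lower after stopping in 13 of 25 members and higher in 1 (15 and 1 adjusted over the list alone), although the list did not pass (fry adjusted p = 0.135, median log2 -0.81, adjusted p = 0.626 with an estimated correlation). The mean of the list was 1.09 and 0.497 in control libraries 1 and 4 and -0.749 and -0.300 in 2 and 3, so the controls overlapped the Post T libraries (-1.17 to -0.279). Fdps fell by 1.68 (SE 0.40, edgeR adjusted p = 0.00899) and Dhcr7 fell by 1.79 (SE 0.46, edgeR adjusted p = 0.0158). On testosterone 0 rose and 1 fell of these 25 (0 and 0 adjusted over the list alone, fry adjusted p = 0.637, 0.903 with an estimated correlation). Stromal and matrix genes had 3 risers and 8 that fell of 28 on testosterone, and 1 and 5 after stopping (4 and 14, then 2 and 8 adjusted over the list alone, fry adjusted p = 0.203 and 0.199). Timp1, an inhibitor of matrix proteases, fell by 3.54 (SE 0.33, edgeR adjusted p = 4.14e-06) on testosterone and fell by 1.74 (SE 0.31, edgeR adjusted p = 0.000815) after stopping. The collagen gene Col15a1 fell by 1.16 (SE 0.185) and fell by 1.32 (SE 0.19), with edgeR adjusted p = 0.000717 and 9.59e-05. Of 18 fibrosis signalling genes, 2 rose and 5 fell on testosterone and 1 rose and 1 fell after stopping (2 and 7, then 1 and 1 adjusted over the list alone, fry adjusted p = 0.164 and 0.654). Tgfb1, a growth factor of fibrosis, fell by 0.87 on testosterone (SE 0.13, edgeR adjusted p = 0.000326) and was at 0.27 after stopping (edgeR adjusted p = 0.203), and these effects differed by -1.14 (edgeR adjusted p = 0.00153).

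Kitl, the ligand of granulosa cells for the receptor Kit, rose by 0.83 (SE 0.12, edgeR adjusted p = 0.000368) on testosterone and by 1.06 (SE 0.12, edgeR adjusted p = 1.41e-05) after stopping. Kit itself rose by 1.79 (SE 0.24, edgeR adjusted p = 0.000137) and by 1.53 (SE 0.24, edgeR adjusted p = 0.000231). Which cells carried the rise of Kit was not tested. Of the androgen responsive genes, Fkbp5, a chaperone of steroid receptors, fell by 1.43 (SE 0.22, edgeR adjusted p = 0.000561) and fell by 1.99 (SE 0.225, edgeR adjusted p = 9.37e-06). Sgk1, a kinase induced by steroids, fell by 2.83 (SE 0.275, edgeR adjusted p = 6.23e-06) and fell by 2.09 (SE 0.27, edgeR adjusted p = 3.55e-05). Rhox5 and Rhox8, homeobox genes, rose after stopping by 1.75 and 1.87 (edgeR adjusted p = 0.0186 and 0.00116). The cell cycle inhibitor gene Cdkn1a fell by 3.14 (SE 0.36, edgeR adjusted p = 3.86e-05) and fell by 1.29 (SE 0.34, edgeR adjusted p = 0.0187). Plin4, a coat protein of lipid droplets, fell by 3.58 (SE 0.61, edgeR adjusted p = 0.00121) and fell by 5.01 (SE 0.65, edgeR adjusted p = 4.13e-05). Among immediate early genes after stopping, 1 rose and 2 fell of 20 (1 and 4 adjusted over the list alone, fry adjusted p = 0.347), and the riser Atf3, a stress-induced transcription factor, rose by 2.51 (SE 0.27, edgeR adjusted p = 5.36e-06).

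The other lists did not pass fry's directional test in either cohort, or in the cohort named. By fry's test for changes in mixed directions, 20 of all 27 lists were called on testosterone and 24 after stopping. Not passing the directional test therefore does not mean that the members were unchanged. The numbers of members that rose and fell are given on testosterone and then after stopping. Granulosa markers had 1 and 0 (1 and 0 adjusted over the list alone), then 1 and 0 (1 and 0 adjusted over the list alone), of 22 (fry adjusted p = 0.592 and 0.654). Theca markers had 2 and 4 (5 and 5 adjusted over the list alone), then 3 and 2 (3 and 3 adjusted over the list alone), of 17 (fry adjusted p = 0.704 and 0.688). Oocyte genes had 2 and 1 (2 and 1 adjusted over the list alone), then 1 and 1 (1 and 1 adjusted over the list alone), of 30 (fry adjusted p = 0.656 and 0.39). Cell cycle genes had 0 and 2 (0 and 2 adjusted over the list alone), then 0 and 2 (0 and 2 adjusted over the list alone), of 33 (fry adjusted p = 0.885 and 0.277). Androgen responsive genes had 0 and 2 (0 and 2 adjusted over the list alone), then 2 and 2 (3 and 4 adjusted over the list alone), of 15 (fry adjusted p = 0.393 and 0.365). Hormone receptors had 1 and 2 (2 and 3 adjusted over the list alone), then 2 and 2 (3 and 2 adjusted over the list alone), of 20 (fry adjusted p = 0.75 and 0.825). Growth factors had 3 and 1 (3 and 2 adjusted over the list alone), then 0 and 1 (0 and 1 adjusted over the list alone), of 23 (fry adjusted p = 0.815 and 0.384). Atresia genes had 2 and 1 (2 and 3 adjusted over the list alone), then 2 and 1 (2 and 1 adjusted over the list alone), of 21 (fry adjusted p = 0.815 and 0.149). Endothelial markers had 1 and 0 (1 and 0 adjusted over the list alone), then 1 and 0 (1 and 0 adjusted over the list alone), of 18 (fry adjusted p = 0.393 and 0.7). Smooth muscle markers had 3 and 0 (4 and 0 adjusted over the list alone), then 0 and 0 (0 and 0 adjusted over the list alone), of 15 (fry adjusted p = 0.494 and 0.586). Surface epithelium markers had 0 and 0 (0 and 0 adjusted over the list alone), then 0 and 0 (0 and 0 adjusted over the list alone), of 13 (fry adjusted p = 0.492 and 0.688). Erythrocyte genes had 0 and 0 (0 and 0 adjusted over the list alone), then 0 and 0 (0 and 0 adjusted over the list alone), of 6 (fry adjusted p = 0.494 and 0.849). Adipocyte markers had 0 and 1 (0 and 1 adjusted over the list alone), then 2 and 1 (2 and 2 adjusted over the list alone), of 14 (fry adjusted p = 0.546 and 0.955). The next are on testosterone alone. Antigen presentation genes had 1 and 0 (0 and 0 adjusted over the list alone) of 17 (fry adjusted p = 0.897). Lymphocyte markers had 2 and 0 (2 and 1 adjusted over the list alone) of 21 (fry adjusted p = 0.494). Cytokines had 1 and 5 (3 and 5 adjusted over the list alone) of 25 (fry adjusted p = 0.592). Oviduct markers had 1 and 1 (1 and 1 adjusted over the list alone) of 11 (fry adjusted p = 0.494). Mitochondrial genes had 0 and 0 (0 and 0 adjusted over the list alone) of 13 (fry adjusted p = 0.546).

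Median, mean and test differed in sign for some of these lists. On testosterone the medians and means were 0.06 and -0.21 for cytokines (test down), 0.13 and -0.000946 for cell cycle genes (up), 0.18 and 0.21 for androgen responsive genes (down), 0.15 and -0.06 for hormone receptors (up) and 0.00517 and -0.02 for growth factors (up). After stopping they were -0.02 and 0.06 for theca markers (up), -0.04 and 0.00128 for androgen responsive genes (down), 0.03 and -0.03 for hormone receptors (up) and 0.04 and -0.07 for adipocyte markers (down).

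The mean of smooth muscle markers was 0.956 in On T library 2 and -0.0903 to 0.164 in the others. The control libraries were not alike. The split of the 8 controls with 182 genes set younger controls 1 and 3 and older controls 2 and 3 against the others. Ces2a had 30 and 37 counts in younger controls 1 and 3 and 744 and 668 in 2 and 4. It had 28 and 349 counts in older controls 2 and 3 and 2215 and 1459 in 1 and 4.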
